A study of Rattus norvegicus with 6 samples.

How the data were processed

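RNA was measured on 6 spotted 2-colour arrays of rat gene probes. Each array paired 1 RNA sample in one dye with RNA of untreated ROSE199 cells, a rat ovarian surface epithelial line, in the other dye. The groups were ROSE199 cells stably carrying an empty vector (1 array), ROSE199 cells stably carrying HMGA2 (2 arrays), ROSEA25 cells given siRNA against EGFP (1 array) and ROSEA25 cells given siRNA against HMGA2 (2 arrays). ROSEA25 was taken as the K-RAS-transformed derivative of ROSE199, since the protocol speaks of ROSE-RAS cells. Stable transfectants were kept in 10 µg/ml blasticidin. The siRNA was given at 0.2 µM in 2 doses 24 h apart, with cells taken 48 h after the first dose, all in 10% serum. Each labelling used 20 µg of RNA.

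The sample was in Cy5 on the 4 arrays of replicate 1 and in Cy3 on the 2 arrays of replicate 2. The 2 arrays of a group were taken as dye-swapped labellings of the same RNA, so there were no replicate cultures in any group. No test between groups was possible on that design, and no p-value is given. The 2 HMGA2 arrays were quantified on another day than the other 4, which all share 1 day.

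The quantification files (header version 5) hold the mean signal and median background intensity of each spot in both channels, per the file headers. The table that the authors deposited beside them holds log2 ratios, with the direction (sample over ROSE199 on every array) read from its correlation with the spot intensities, which was 0.848, 0.844, 0.948, 0.841, 0.895 and 0.924 in the order of the arrays. Its column medians are -0.03, -0.04, 0.03, 0.09, -0.10 and 0.20. How its values were centred and corrected for background is not given in the sources used here, and the table served as an alternative.

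Each array holds 1760 spots, of which 37 are blank and 325 carry beta actin. Spots of the same name were averaged into 311 features, of which 18 are unnamed clones. Spots marked as poor by the quantification software (24, 25, 21, 47, 25 and 64 per array) were left out. Housekeeping PCR fragments in a separate part of the array were not analysed here. Background was subtracted by the normexp method with an offset of 50, and ratios were centred by a loess curve over intensity per array (span 0.3, 4 iterations) with blank and beta actin spots given no weight. R 4.3.3 and limma 3.58.1 were used. Arrays were not scaled to one spread.

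Each feature was fitted by least squares with 1 value per group and 1 dye term over the 6 arrays. The fit leaves 1 residual per feature, so the spread was pooled over the 311 features, as a scaled median absolute residual (SD 0.169; the root mean square was 0.229). The single-array groups are fitted exactly, so this spread comes from the HMGA2 and siHMGA2 arrays only. This gave a pooled standard error of 0.22 for HMGA2 against empty vector and for siHMGA2 against siEGFP, 0.19 for empty vector and siEGFP against ROSE199, and 0.12 for HMGA2 and siHMGA2 against ROSE199. These errors cover labelling and hybridization only. The same SD served for all features and groups, so it can understate the error of single features. Against ROSE199 the 2 siHMGA2 arrays read -1.22 and -3.22 for T16 and -1.91 and -3.69 for SM22, gaps that hold dye effects as well. Other features were closer, such as Collagen alpha (-3.22 and -3.47). A feature passed when its log2 difference was at least 1 in size, over 2 pooled standard errors, and of the same sign in the Cy5 arrays alone. In the single-array groups the dye term came from the other groups, so a dye effect specific to 1 array stays in their values.

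The median spot SD on the log2 scale was 0.06, 0.06, 0.04, 0.06, 0.08 and 0.13 per array. The swapped arrays correlated at 0.838 for HMGA2 and 0.886 for siHMGA2. A feature counted as above blank in a channel when its net signal exceeded the mean of the blank spots by 3 of their SD. In the sample channel 1, 1, 1, 25, 1 and 5 features did not, and in the ROSE199 channel 1, 1, 1, 6, 1 and 35. A group counted as above blank when any of its arrays was, and ROSE199 when its channel was on any array. Where one side of a comparison was not above blank, its fold is given as a bound: the brighter group's mean over the dimmer group's mean, each dim value being raised to the lowest signal among features above blank. These means are per channel after loess and quantile normalization of the average intensity between arrays, and are open to dye bias. Where the bound was under 1 or neither side was above blank, no fold is given. Alpha tubulin was saturated on the empty-vector array and on HMGA2 replicate 2.

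Of the 6 comparisons, 3 were the main ones (HMGA2 against empty vector, siEGFP against ROSE199 and siHMGA2 against siEGFP) and 3 set the other groups against ROSE199. Relations between the 3 main ones were also computed. For each relation the correlation and covariance from shared arrays alone were simulated with the pooled errors and no difference at any feature. Such a correlation is that of errors alone, so an observed correlation cannot be read against it. The covariance shows how much these errors could add. Features named in the text are, per comparison, up to 15 passing in each direction (filled to 10 by size where fewer pass), the targeted genes HMGI-C and K-ras, up to 4 members of each gene list, and the 2 highest and 2 lowest unnamed clones. Gene names are those printed on the array. Of 86 features tied to a list symbol, 23 carried the symbol itself, 18 were joined through a synonym table of the rat genome (GRCr8) and 45 through a textbook name. For 10 of these the family member is not stated by the name, among them Collagen alpha, IGFPBP and LOXRP.

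The 18 gene lists had these numbers of members measured: RAS-MAPK feedback and early response 19, secreted regulators (TGF-beta, IGF and others) 11, extracellular matrix 9, proteases and inhibitors 8, actin and contractile genes 8, cell cycle 8, adhesion and surface receptors 7, epithelial and ovarian surface epithelium 5, mesenchymal transition 4, HMGA proteins and reported HMGA2 targets 4, housekeeping 4, and glycolysis and hypoxia 3. Protein folding and stress had 2, the interferon response 1 and translation 1, and these were read by gene. Mitochondrial respiration, cholesterol and lipid, and markers of other cell types had 0 and were left out. A list's median was placed among the medians of 10000 random lists of features matched for intensity, and lists outside the percentiles 2.5 to 97.5 are named. TSC36 and Follistatin related protein were tied to the same gene and count separately.

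The fit was tested on simulated data with the layout of the 6 arrays. Of 30 features given a log2 change of 1.5, 30, 29 and 29 passed in the 3 main comparisons. Of 251 features given no change, 3, 0 and 1 passed.

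Groups, comparisons, rules, lists and most alternatives were chosen before the data were examined. The alternatives were plain, offset 10 or no background correction, poor spots kept, the median of spots, dim features left out, centring by the median, by print-tip or by housekeeping genes, scaling of arrays, Cy5 arrays only, no dye term, the deposited ratios, a smaller size limit of log2 0.585, and leaving out each array of a pair. Centring on beta actin spots, beta actin in the loess, blank spots as background, a dye term per quantification day, the brighter features alone (above the median intensity), list medians under 2 further settings, and list medians with features not above blank at their bound (left out where they had none or were saturated) were added after the data were seen. Some of these settings coincide and are not separate checks. Centring by the median, housekeeping genes or beta actin differs by 1 constant per array, so correlations and list percentiles are the same. For siEGFP against ROSE199, Cy5 arrays only and no dye term are the same fit. For siHMGA2 against siEGFP, Cy5 arrays only and the dye term per day both give replicate 1 minus siEGFP. Leaving out siHMGA2 replicate 2 or either HMGA2 array gives it too.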

Results

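HMGI-C, the array's name for HMGA2, was the targeted gene and was measured on all 6 arrays. Against ROSE199 RNA its log2 ratio was 0.26 in the empty-vector cells, 3.70 and 3.33 in the 2 HMGA2 arrays, 2.40 in ROSEA25 cells with siEGFP, and 1.2 and 1.59 in ROSEA25 cells with siHMGA2. HMGI-C was therefore 11.4-fold higher in the HMGA2 transfectants than in ROSE199, and 5.30-fold higher in the RAS-transformed control. With siHMGA2 it was 2.01-fold lower than with siEGFP (-1.01, pooled standard error 0.22; -0.44 without siHMGA2 replicate 1 and -0.15 with arrays scaled to one spread, so the knock-down was not stable) and still 1.40 above ROSE199 on the log2 scale. K-ras was 0.03 in the empty vector, -0.29 and -0.11 with HMGA2, 4.25 with siEGFP, and 4.82 and 4.60 with siHMGA2. There is 1 RNA sample per group, so every difference below is between single cultures.

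**Figure D1:**
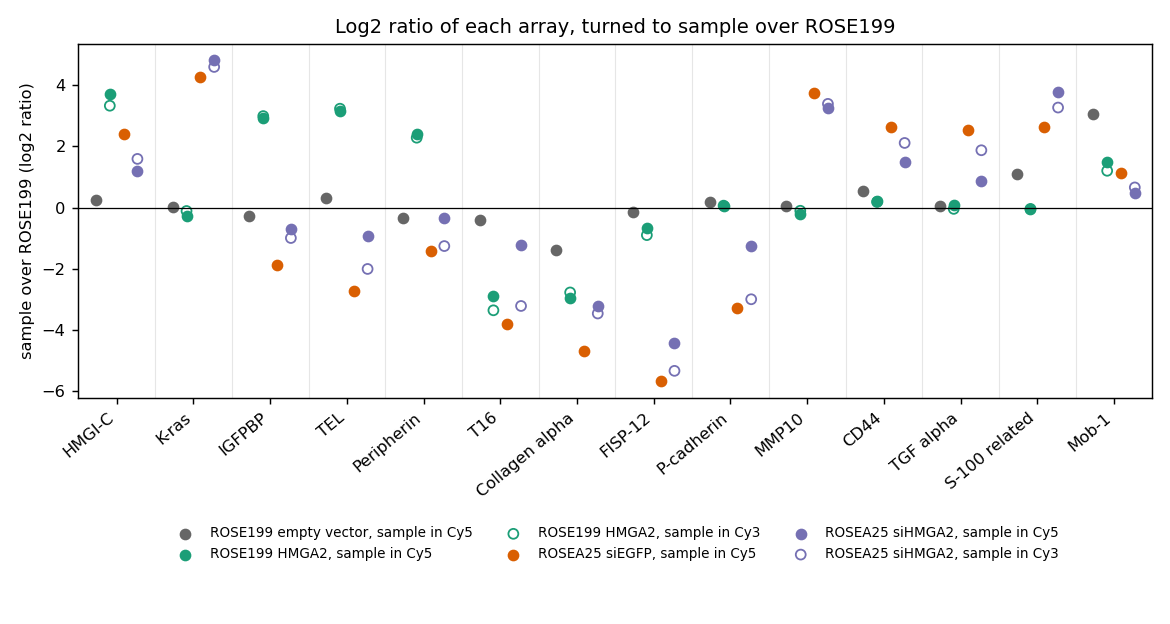
Log2 ratio of sample over ROSE199 RNA on each of the 6 arrays for selected genes, grouped by cell line and treatment. HMGI-C was highest in the HMGA2 arrays (3.70 and 3.33), while K-ras was high in the 3 ROSEA25 arrays alone (4.25, 4.82 and 4.60).

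ROSE199 cells with HMGA2 had a small set of genes higher than cells with the empty vector. Beside HMGI-C itself (3.25, 9.52-fold), IGFPBP (3.28, 9.74-fold), TEL (3.15, 8.85-fold) and Peripherin (2.95, 7.74-fold), a neuronal intermediate filament, were highest. Sortilin (1.68), NO3 (1.58), Ril (1.51), the transcription factor N-myc (1.30), Hepatocellular carcinoma antigen (1.29), P53 binding protein (1.14), DOC-2 (1.12), Steroid sensitive gene (1.08), Cav-1 (1.04) and MEN1 (1.03) also passed as higher. Lower were T16 (-2.09, 4.24-fold), Balb aldose reductase related (-1.98, 3.96-fold), the chemokine Mob-1 (-1.70), Collagen alpha (-1.44), Ahnak (-1.40), Sex comb on midleg homolog (-1.36), the prostaglandin synthase Cox2 (-1.31), FHL2 (-1.26), Serum inducible kinase (-1.09) and MYB-binding protein (-1.02). In all, 14 of 311 features were higher and 10 lower.

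K-ras did not pass (-0.22). None of the 19 RAS-MAPK genes passed, and their median of -0.24 lay at percentile 1.32 of matched lists, with Fra-1 at -0.90, HB-EFG at -0.85, TDAG51 at -0.78 and c-myc at -0.61. That position was inside the range under 7 of 10 alternatives, for instance percentile 7.5 for RAS-MAPK feedback and early response after scaling of the arrays. Among these 10, the centrings by the median, housekeeping genes and beta actin share 1 position. Of the 4 HMGA proteins and reported targets only HMGI-C passed, and P16 (ink4a) (-0.69), c-myc (-0.61) and JunB (-0.41; 0.076 with beta actin centring, HMGA2 minus empty vector) were negative. This list's median of -0.51 lay at percentile 1.66, and at 13.7 under median centring (HMGA proteins and reported HMGA2 targets).

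The other lists lay inside the matched range in this comparison. Extracellular matrix genes had a median of -0.05 with T16 and Collagen alpha lower, and epithelial genes 0.36 with DOC-2 higher, E-cadherin at -0.85 and WT1 at 0.36. Secreted regulators had a median of -0.01 with IGFPBP alone passing, and actin and contractile genes -0.28 with Cav-1 higher and P9ka42a at -0.88. Mesenchymal genes (-0.46), proteases (-0.16), adhesion genes (-0.24), cell cycle genes (-0.05), glycolysis genes (-0.06) and housekeeping genes (-0.44) held no passing member. Of the housekeeping genes, GAPDH (-0.52; 0.070 with beta actin centring, HMGA2 minus empty vector) and beta actin (-0.49) were negative and HPRT positive (0.27). Alpha tubulin was saturated on the empty-vector array, and the list's median without it was -0.49. The ribosomal S9 was at -0.52, and of the stress genes P5 protein was at 0.88 and GADD153 at 0.31.

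The HMGA2 arrays were quantified on a day of their own, and HMGA2 and day cannot be told apart in this comparison. Centring on beta actin gave 34 higher and 7 lower (82.9% higher, against 58.3%), and without HMGA2 replicate 1 there were 27 higher, while 10 of the 24 features passed under every alternative run apart from the one on brighter features alone, among them HMGI-C, IGFPBP, TEL, Peripherin, Sortilin and Mob-1.

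Against untreated ROSE199 RNA, HMGA2 cells had HMGI-C (3.51), TEL (3.20), IGFPBP (2.96) and Peripherin (2.35) highest. NO3 (1.82), RPT-1r (1.38), Hepatocellular carcinoma antigen (1.35), Mob-1 (1.34), H-rev107 (1.33), N-myc (1.27), Trancript associated (1.17), Sortilin (1.04), Mama (1.04) and MEN1 (1.01) made up the 14 higher features. The 7 lower ones were T16 (-3.13), Collagen alpha (-2.87), Ahnak (-2.41), Thrombospondin 1 (-1.60), the smooth muscle protein SM22 (-1.51), the unnamed clone ESTAA791601 (-1.36) and Cox2 (-1.16). The extracellular matrix list had a median of -0.61 (percentile 0.075) with 3 of 9 members lower, and the HMGA list -0.69 (percentile 0.565). Without HMGA2 replicate 2 there were 15 lower features (HMGA2 minus ROSE199, features lower).

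The empty vector alone differed from ROSE199 at 9 features. Mob-1 (3.04, 8.24-fold), Mama (1.61), Interferon induced gene (1.24) and Balb aldose reductase related (1.06) were higher. Thrombospondin 1 (-1.55), Collagen alpha (-1.42), Lox (-1.24), which crosslinks collagen, T16 (-1.04) and Ahnak (-1.01) were lower. Extracellular matrix genes had a median of -0.74, below all matched lists (percentile 0), with 4 of 9 lower, and Fibrillin-1 at -0.74 and Osteonectin at -0.40 not passing. The lower Mob-1 and Balb aldose reductase related values of HMGA2 cells against the empty vector thus start from a high empty-vector value: Mob-1 was higher than ROSE199 in both. Centring on beta actin, housekeeping genes or the median left 3 features higher here and 8, 7 and 8 lower, so the share higher moved from 44.4% to 27.3%, 30% and 27.3%. Leaving out 1 HMGA2 array gave 11 lower features, and leaving out 1 siHMGA2 array 3 (empty vector minus ROSE199, features lower).

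RAS-transformed ROSEA25 cells with siEGFP differed far more from ROSE199, with 35 features higher and 48 lower. K-ras (4.24, 18.9-fold) and Neuritin (4.10, 17.2-fold) were highest, with MMP10 (3.82, 14.1-fold), Hepatocellular carcinoma antigen (3.74, 13.4-fold) and RPT-1r (3.56, 11.8-fold). CD44 (2.78), the EGF receptor ligand TGF alpha (2.74), E1B 19k Bcl-2 BP (2.65), Cyclooxygenase 1 (2.54), S-100 related (2.5), MMP-3 (2.49), Cpg21 (2.47), HMGI-C (2.41), Prkar2b (2.24) and CyclinD1 (2.08) followed. The lowest were FISP-12 (-5.97, 62.9-fold), the unnamed clone ESTAA673854 (-5.08), Collagen alpha (-4.70, 26.0-fold), SM22 (-4.55, 23.5-fold) and Basonuclin (-4.33, 20.1-fold). Follistatin related protein (-3.92), Thrombospondin 1 (-3.77), P-cadherin (-3.73), TSC36 (-3.57), NAP-22 (-3.35), TRPM-2 (-3.33), Par4 (-3.32), Lox (-3.13) and Cyr61 (-3.04) were also low.

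For 4 of the lower features the siEGFP signal was not above blank, and these are bounds: T16 at least 6.85-fold lower, Frat3 at least 3.44-fold, IGFPBP at least 2.99-fold and P53 binding protein at least 1.79-fold. The siEGFP values come from 1 array with the sample in Cy5 and carry any dye effect specific to it, and no group separates RAS from siRNA transfection or the derivation of the line. Of the 83 features, 42 passed under every alternative run apart from the one on brighter features alone.

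The RAS-MAPK list was shifted up (median 0.54, percentile 99.2), with 7 of 19 passing as higher: TGF alpha, CD44, Cpg21, CyclinD1, Sprouty2 (1.49), Fra-1 (1.40) and TDAG51 (1.18). Mkp1 (-0.97) and c-myc (-0.53) were negative without passing. Extracellular matrix genes were shifted down (median -0.92, percentile 0.94; -0.77 and 1.57 with Fibrillin-1 and T16, not above blank with siEGFP, at their bounds), with Collagen alpha, T16, Thrombospondin 1 and Lox lower and LOXRP (1.46) higher. Epithelial genes were lower as well (median -1.98, percentile 2.26): P-cadherin, E-cadherin (-2.55), Megakaryocyte potenciating factor (-1.98) and WT1 (-1.41) passed, and DOC-2 (-0.74) did not. The RAS-MAPK and extracellular matrix positions lay outside the range in all 10 alternatives, and that of the epithelial and ovarian surface epithelium list in 9, the exception being the deposited ratios (percentile 4.91). The centrings by 1 constant share 1 position, as do Cy5 arrays only and no dye term, so these are not 10 separate checks.

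Inside the matched range, 3 of 8 protease genes were higher (MMP10, MMP-3 and Cathepsin D at 1.29; median 0.48), with PAI1 at 0.24. Of 11 secreted regulators 5 were lower, namely FISP-12, Follistatin related protein, TSC36, Cyr61 and IGFPBP (median -0.60, inside the range; -1.09 and percentile 1.11, outside it, with IGFPBP at its bound and PDGF receptor, with no bound, left out). PDGF receptor was at 0.32 in the fit, so the shift to -1.09 rests on removing a member of the other sign. Actin and contractile genes split, P9ka42a (1.99) and Cav-1 (1.12) being higher and SM22 and TPM2 (-1.12) lower (median -0.13), and mesenchymal genes split between P9ka42a and the TGF-beta receptor TGFBT2R (-2.27; median -0.32). CyclinD1 was the only one of 8 cell cycle genes to pass (median -0.05), with Ki-67 at 0.41 and P27 kip at -0.69. CD44 was the only one of 7 adhesion genes to pass, with Syndecan-1 at 0.96. The median of the adhesion genes was -0.10, and -0.23 with Cx43, EGFR and Thy-1, not above blank with siEGFP, at their bounds. Glycolysis genes had a median of 0.28, the HMGA list 0.21 and housekeeping genes 0.01, with HPRT lower (-1.49). Outside these, GADD153 (1.62) and Mob-1 (1.10) were higher, P5 protein was at -0.48 and S9 at 0.22. Housekeeping centring moved the median of all features here by 0.31 and gave 75 higher and 38 lower (66.4% higher against 42.2%).

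**Figure D2:**
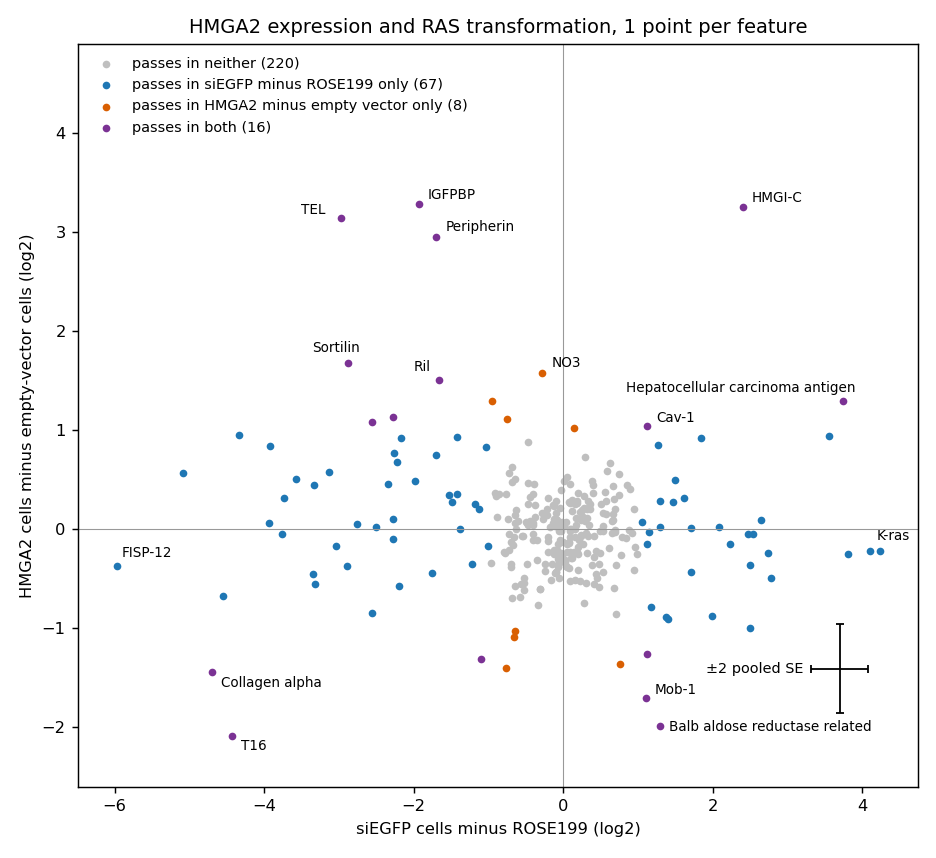
Log2 difference of siEGFP-treated ROSEA25 from ROSE199 (horizontal) against that of HMGA2 from empty vector (vertical), 1 point per feature. The correlation was -0.10, and 7 features higher with HMGA2 were lower in ROSEA25.

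The HMGA2 and the ROSEA25 differences had little in common across the 311 features. The correlation was -0.10 (rank -0.11). Errors of the shared fit alone gave -0.17 (-0.28 to -0.05), a correlation of errors that cannot be read against it. The covariance was -0.089 against -0.013 in simulation. HMGI-C, Cav-1 and Hepatocellular carcinoma antigen were higher in both comparisons (3 features; 1.58 from independent lists), and Collagen alpha, T16 and Cox2 lower in both (3; 1.54). IGFPBP, P53 binding protein, Peripherin, Ril, Sortilin, Steroid sensitive gene and TEL were higher with HMGA2 and lower in ROSEA25 (7; 2.16), and Mob-1, FHL2 and Balb aldose reductase related the reverse (3; 1.13). Part of any excess may come from the shared dye term, and without HMGA2 replicate 1 the correlation of HMGA2 minus empty vector with siEGFP minus ROSE199 was -0.37.

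With siHMGA2, 27 features were higher and 7 lower than with siEGFP in ROSEA25 cells. Cyr61 (1.84, 3.59-fold), SM22 (1.75, 3.37-fold), FAH (1.70, 3.24-fold), Protein tyrosine phosphatase delta (1.61), P-cadherin (1.60, 3.03-fold), Sortilin (1.55), MUK2 (1.54), TSC36 (1.51), TEL (1.5), Par4 (1.46), Basonuclin (1.43), H-rev107 (1.40) and Collagen alpha (1.36) were higher, as was the unnamed clone ESTAA673854 (2.75). T16 was at least 1.47-fold and IGFPBP at least 1.69-fold higher, siEGFP being not above blank, and for Frat3 and P53 binding protein no fold is given. PS-PLA1 (-1.59), TGF alpha (-1.37), Cyclooxygenase 1 (-1.30), Cpg21 (-1.24) and HMGI-C (-1.01) were lower. Ha-ras also passed as lower (-1.41), but it read -1.36 and 1.28 on the 2 siHMGA2 arrays of opposite dyes and 0.065 on the siEGFP array. Its difference was -1.43 in Cy5 arrays alone and -0.10 with no dye term. SFB1 posphatase also passed as lower, above blank on neither side. Just under the size limit were CD44 (-0.99), Prkar2b (-0.95) and RPT-1r (-0.89), and K-ras was at 0.47.

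The RAS-MAPK list was shifted down (median -0.22, percentile 0.48) with TGF alpha and Cpg21 passing, Fra-1 at -0.69 and CyclinD1 at -0.51. This list was up in siEGFP minus ROSE199 (0.54), where the siEGFP array enters with the opposite sign. Error of that array or compressed ratios would thus also move it down, and against ROSE199 it stayed at percentile 99.955 with siHMGA2. The epithelial, extracellular matrix and secreted lists, negative there and positive here, carry the same limit. Mesenchymal genes were at the upper edge (0.79, percentile 97.6), TGFBT2R (1.36) and P9ka42a (1.32) being higher. Without a dye term the list RAS-MAPK feedback and early response had a median of -0.03 (percentile 31.5), and the mesenchymal transition list lay inside the range under 7 of 10 alternatives. Of these 10, the centrings by 1 constant share 1 position, as do Cy5 arrays only and the dye term per day. Epithelial genes had a median of 0.73 (percentile 97.2) with P-cadherin and E-cadherin (1.13) higher, DOC-2 at 0.73 and WT1 at 0.71. Extracellular matrix genes had 3 of 9 higher (Collagen alpha, T16 and Thrombospondin 1 at 1.13; median 0.25, or 0.40 with T16 at its bound and Fibrillin-1, with no bound, left out) and secreted regulators 5 of 11 (Cyr61, TSC36, FISP-12 at 1.09, Follistatin related protein at 1.17 and IGFPBP; median 0.26, percentile 83.4). With IGFPBP at its bound and PDGF receptor left out, the secreted regulators' median was 0.51, outside the range at percentile 98.4. PDGF receptor was at -0.33 in the fit and was left out for its bound under 1. The shift thus rests on removing a member of the other sign and decides nothing. The percentile of the epithelial genes was then 97.8, also outside, though all members and the median were unchanged and only the matched lists differed. Under median, housekeeping and beta actin centring, extracellular matrix (percentile 97.7) and secreted regulators (99.4) lay outside the range too.

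Actin and contractile genes had a median of 0.05 with SM22 and P9ka42a higher, and the HMGA list 0.04 with HMGI-C lower. No member passed among proteases (-0.24; MMP1 at -0.68), cell cycle genes (0.12; P27 kip at 0.44), adhesion genes (0.05, or 0.30 with bounds), glycolysis genes (-0.28) and housekeeping genes (0.20). Mob-1 was at -0.53, S9 at -0.24, GADD153 at 0.56 and P5 protein at -0.29.

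Only 3 of the 34 features (FAH, Frat3 and ESTAA673854) passed under every alternative run apart from the one on brighter features alone. For Frat3 siEGFP was not above blank and no higher signal is shown. Without siHMGA2 replicate 1 there were 12 higher and 4 lower features: FAH (1.62) and Cyclooxygenase 1 (-1.35) were about as large, PS-PLA1 (-2.14) and Cpg21 (-1.58) larger, while Sortilin was at 0.20, TEL at 0.65, Cyr61 was at 0.64, SM22 at 0.29, P-cadherin at 0.30, TGF alpha at -0.52 and HMGI-C at -0.44. Leaving out any 1 of the other paired arrays gave 31 and 11, each time by the same estimate, siHMGA2 replicate 1 minus siEGFP in Cy5. These are therefore 1 check and not 3, and they set siHMGA2 replicate 1 against replicate 2. With arrays scaled to one spread HMGI-C was at -0.15, and Collagen alpha (-0.17) and FISP-12 (-0.61) were on the lower side. The share of higher features was 79.4%, and 61% after median centring (25 and 16), 64.5% by print-tip and 47.2% after housekeeping centring (17 and 19), which moved the median of all features by -0.24.

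**Figure D3:**
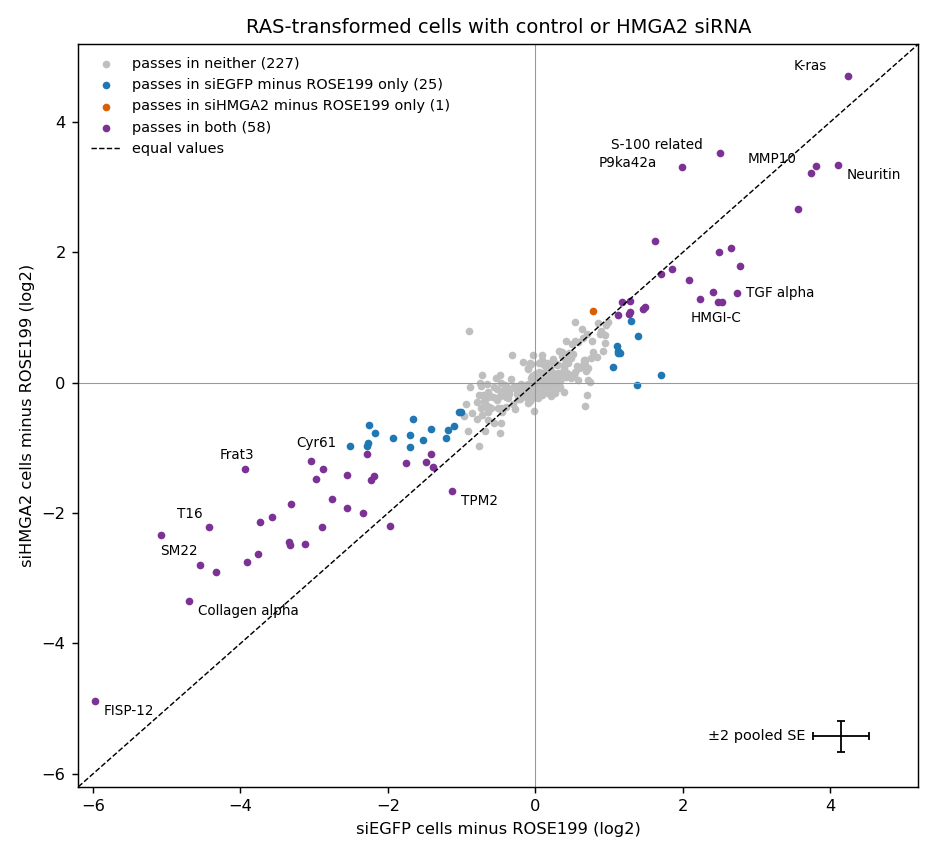
Log2 difference from ROSE199 in ROSEA25 cells with siEGFP (horizontal) and with siHMGA2 (vertical), 1 point per feature at its fitted value. Of the 83 features passing with siEGFP, 76 had a smaller or opposite difference with siHMGA2, for example FISP-12 (-5.97 and -4.88) and MMP10 (3.82 and 3.32), while K-ras (4.24 and 4.71) lay further out.

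Against ROSE199, siHMGA2-treated ROSEA25 cells still had 27 features higher and 32 lower. K-ras (4.71, 26.2-fold), S-100 related (3.53), Neuritin (3.35), MMP10 (3.32), P9ka42a (3.31), Hepatocellular carcinoma antigen (3.23), RPT-1r (2.67), the stress gene GADD153 (2.18), E1B 19k Bcl-2 BP (2.07), MMP-3 (2.01), CD44 (1.79), Trancript associated (1.74), BCSC-1 (1.67), CyclinD1 (1.57) and HMGI-C (1.40) were higher. FISP-12 (-4.88, 29.5-fold), Collagen alpha (-3.34), Basonuclin (-2.90), SM22 (-2.80), Follistatin related protein (-2.75), Thrombospondin 1 (-2.63), TRPM-2 (-2.48), Lox (-2.47), NAP-22 (-2.45), Cca1 (-2.22), T16 (-2.22), Megakaryocyte potenciating factor (-2.20), P-cadherin (-2.13), TSC36 (-2.07) and LOT1 (-2.0) were lower. RAS-MAPK genes were high (median 0.46, percentile 99.955; 6 of 19 higher), and extracellular matrix (-0.97, percentile 0.18) and epithelial genes (-1.42, percentile 1.38; 3 of 5 lower) low. Secreted regulators had a median of -0.39 (percentile 1.81; 4 of 11 lower). Of these 4 lists, extracellular matrix lay outside the range under all 10 alternatives. No dye term and the dye term per day leave the values of this comparison unchanged, and the centrings by 1 constant share 1 position. With the deposited ratios the other 3 lay inside it (percentiles 80.7, 3.39 and 21.2 for RAS-MAPK, epithelial and secreted genes), as did the secreted regulators under 4 further alternatives and the epithelial genes with Cy5 arrays only.

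Of the 83 features that passed in siEGFP-treated cells, 76 had the opposite sign in siHMGA2 minus siEGFP, 61 of them by over 2 pooled standard errors. With no change between siHMGA2 and siEGFP, simulation gave opposite signs for a median of 48 of 83 and at most 70, since both differences hold the siEGFP array. The simulated errors were the pooled ones, which do not measure the siEGFP array's own error. The median share of the siEGFP difference that was gone with siHMGA2 was 0.353, against 0.022 (at most 0.072) simulated from shared arrays. It was 0.405 for the 48 lower features and 0.228 for the 35 higher ones. HMGI-C itself had lost 0.419 of its difference. Of the features lower with siEGFP, 24 passed as higher with siHMGA2 (4.17 from independent lists, and at most 7 features passing at all in the simulation with no change), among them Cyr61, SM22, P-cadherin, TSC36 and Basonuclin. These 24 include Frat3, T16, IGFPBP and P53 binding protein, not above blank with siEGFP, and for Frat3 and P53 binding protein no higher signal is shown. Among the 79 features above blank in both comparisons the share was 0.330, and 26 passed in opposite directions, against 30 of 83. That rule asks for 1 array per group only, so signals near blank on single arrays remain in the 79. The ROSE199 channel of siHMGA2 replicate 2 had 35 features of the array not above blank. TGF alpha, Cyclooxygenase 1, Cpg21, PS-PLA1, HMGI-C and Ha-ras went the other way (6; 0.788), Ha-ras being higher with siEGFP through its dye term only. The correlation of the 2 differences was -0.79 (rank -0.77). Arrays simulated with no difference at any feature gave -0.84 (-0.88 to -0.80) through the shared siEGFP array. That is the correlation of errors alone, so -0.79 cannot be read against it. The covariance, which keeps the size of the differences, was -0.665 against -0.065 simulated. Without siHMGA2 replicate 1 the share was 0.191, and with arrays scaled to one spread it was 0.116, with opposite signs in 36 of the 56 features then passing with siEGFP.

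The differences with HMGA2 in ROSE199 and with siHMGA2 in ROSEA25 did not mirror each other. The correlation was 0.11 (rank 0.06; 0.14 simulated, 0.02 to 0.25) and the covariance 0.043 (0.013 simulated). The simulated correlation is again that of errors alone and cannot be read against 0.11. IGFPBP, Ril, Sortilin, TEL and P53 binding protein passed as higher in both comparisons (5; 1.22 from independent lists), though for P53 binding protein no higher signal with siHMGA2 is shown, Collagen alpha and T16 were lower with HMGA2 and higher with siHMGA2 (2; 0.868), and HMGI-C alone was higher with HMGA2 and lower with siHMGA2. Without HMGA2 replicate 1 the correlation of HMGA2 minus empty vector with siHMGA2 minus siEGFP was 0.41.

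**Figure D4:**
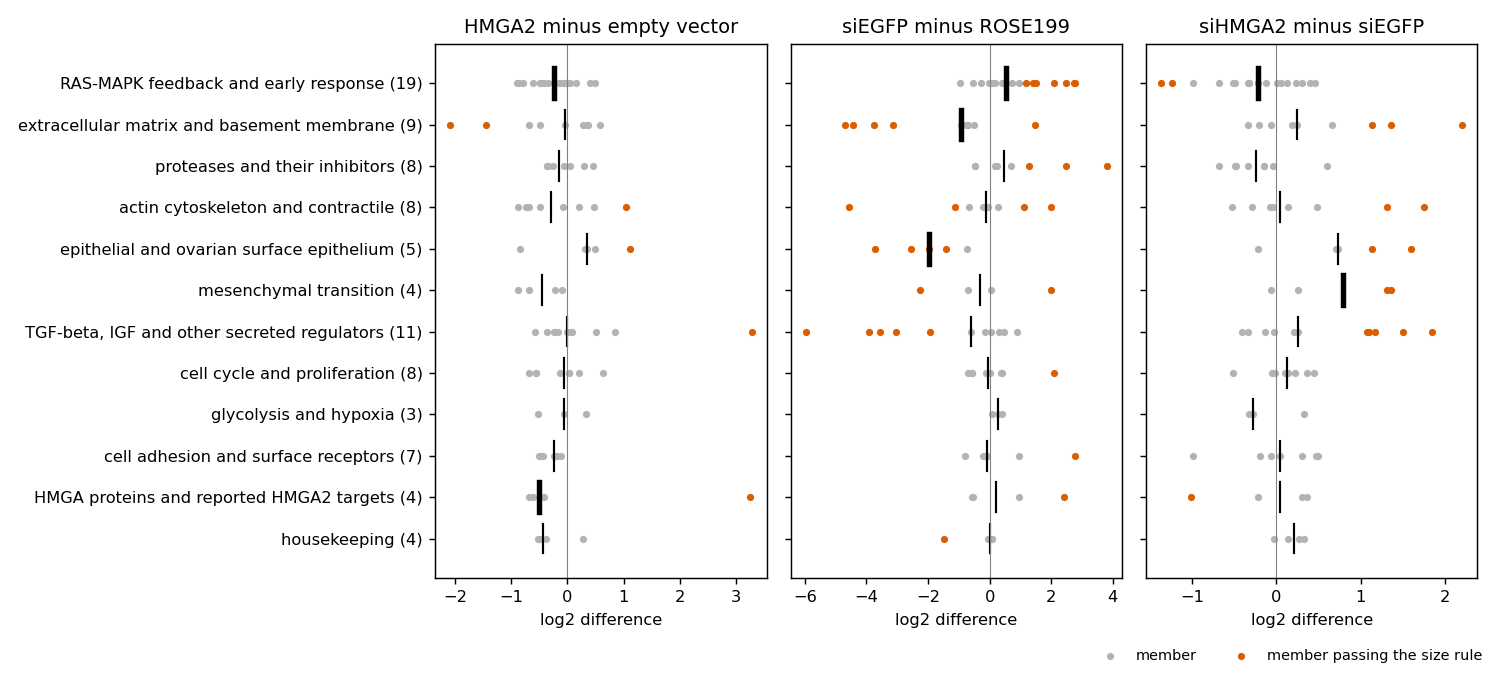
Log2 difference of each member (points) and median (bar) of each gene list with at least 3 measured members in the 3 main comparisons. Thick bars mark medians outside the matched range. Extracellular matrix genes had medians of -0.05 for HMGA2 against empty vector, -0.92 for siEGFP against ROSE199 and 0.25 for siHMGA2 against siEGFP. The medians of RAS-MAPK genes were -0.24, 0.54 and -0.22 in the same order.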

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

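Centring on beta actin, beta actin in the loess, blank spots as background, the dye term per quantification day, the brighter features alone, list medians under scaling and housekeeping centring, and list medians with dim features at their bounds were chosen only after the data were seen. Of the values that answer a comparison, 369 stayed within their limit across settings and 82 moved, with settings that coincide each counted. Some of the 369 could not move, such as correlations under the smaller size limit or HMGA2 against ROSE199 without 1 siHMGA2 array. The tally is therefore no measure of stability. The limit was 1.5-fold for a count, whichever features it held. For a correlation or the share it was the SD over the fits without 1 paired array, so those fits were judged by their own spread. Print-tip loess kept 18 of the 34 features of siHMGA2 against siEGFP and 51 of the 83 of siEGFP. The deposited ratios kept 17 and 68, and plain background subtraction 33 and 83. Of all passing differences, 4 of 83 for siEGFP, 5 of 34 for siHMGA2 against siEGFP and 1 of 59 for siHMGA2 against ROSE199 changed direction under some setting, among them 6 of genes named here (5 genes), and no median of a list outside the range did. The median of all features moved by over 0.1 under housekeeping centring (0.31 for siEGFP, 0.20 for siHMGA2 against ROSE199, -0.24 for siHMGA2 against siEGFP), beta actin centring (0.21 for HMGA2 against empty vector, 0.17 for HMGA2 against ROSE199, -0.24 for siEGFP) and the deposited ratios (-0.12, 0.13 and -0.15 in the 3 main comparisons, 0.11 for siHMGA2 against ROSE199). The cause of these differences was not tested.

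With no background correction, HMGA2 against empty vector had 8 features higher, siHMGA2 against siEGFP 3 lower, empty vector against ROSE199 3 lower and siHMGA2 against ROSE199 16 higher. Lists outside the range were 1 for siHMGA2 against siEGFP and 2 for the empty vector. Median centring gave 16 lower with siHMGA2 against siEGFP and 8 lower in the empty vector, with 4 and 3 lists. Print-tip loess gave 11 lower with siHMGA2 against siEGFP, and turned Cathepsin D in siEGFP minus ROSE199 (-0.084) and TEL (-0.015) and Thrombospondin 1 (-0.26) in siHMGA2 minus siEGFP. Housekeeping centring gave 75 higher with siEGFP and 17 higher and 19 lower with siHMGA2 against siEGFP, with 4 lists there and 3 for the empty vector.

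Scaling the arrays to one spread gave 23 higher and 17 lower for HMGA2 against empty vector, 19 higher with siEGFP, 7 higher and 2 lower for siHMGA2 against siEGFP, and 13 higher and 11 lower in the empty vector. There the correlation of siEGFP minus ROSE199 with siHMGA2 minus siEGFP was -0.19, 36 of 56 features had opposite signs, the share was 0.116, and lists outside the range were 1, 5 and 1 in the 3 main comparisons. Collagen alpha (-0.17) and FISP-12 (-0.61) turned in siHMGA2 minus siEGFP. Cy5 arrays only gave 11 lower for siHMGA2 against siEGFP. No dye term left 1 list for HMGA2 against empty vector.

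The deposited ratios (series matrix values) gave 56 higher with siEGFP, 27 lower for siHMGA2 against siEGFP, 9 higher for HMGA2 against ROSE199, a share of 0.591, and 0 lists for HMGA2 against empty vector and 1 for siHMGA2 against ROSE199. Cathepsin D in siHMGA2 minus ROSE199 turned to -0.22. The smaller size limit gave, higher and lower, 30 and 26, 64 and 80, 49 and 19 in the main comparisons, and 11 and 16, 29 and 25, 46 and 51 for empty vector, HMGA2 and siHMGA2 against ROSE199, with 130 features of opposite sign.

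Centring on beta actin gave 34 higher for HMGA2 against empty vector, 12 lower for siHMGA2 against siEGFP, 8 lower in the empty vector and 22 higher for HMGA2 against ROSE199, with 4 lists for siHMGA2 against siEGFP and 3 for the empty vector. The dye term per quantification day gave 11 lower for siHMGA2 against siEGFP and 11 lower in the empty vector. The brighter features alone held 7 higher and 6 lower, 16 higher with siEGFP, 0 lower for siHMGA2 against siEGFP, 3 lower in the empty vector, 6 higher and 4 lower for HMGA2 against ROSE199, 15 higher for siHMGA2 against ROSE199, and 48 of opposite sign.

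Leaving out 1 array of a pair gave 13 to 27 higher and 13 to 14 lower for HMGA2 against empty vector, 34 to 36 and 46 to 49 for siEGFP, 12 to 31 and 4 to 11 for siHMGA2 against siEGFP, 4 to 6 and 3 to 11 for the empty vector, 13 to 16 and 7 to 15 for HMGA2 against ROSE199, and 25 to 28 and 26 to 38 for siHMGA2 against ROSE199. The correlation of HMGA2 minus empty vector with siEGFP minus ROSE199 ran from -0.37 to 0.0064, that of siEGFP minus ROSE199 with siHMGA2 minus siEGFP from -0.81 to -0.60, and that of HMGA2 minus empty vector with siHMGA2 minus siEGFP from -0.0077 to 0.41. Features of opposite sign ran from 62 to 78 and the share from 0.191 to 0.398. Without 1 paired array the fit leaves no residual, so several of these estimates coincide.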

Other observations

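The chemokine gene Mob-1 was highest in the vector control: it was 8.24-fold higher than ROSE199 with the empty vector (3.04), and higher with HMGA2 (1.34) and in ROSEA25 with siEGFP (1.10), and at 0.57 with siHMGA2. Mama went with it in the vector cells (1.61 with the empty vector, 1.04 with HMGA2), and Interferon induced gene was higher with the empty vector (1.24). The difference of Mob-1 and Mama from ROSE199 was thus present without HMGA2. In ROSEA25 cells 7 of the 83 features that passed with siEGFP lay further from ROSE199 with siHMGA2, against the trend of the others. P9ka42a was at 1.99 and then 3.31, S-100 related at 2.5 and 3.53, GADD153 at 1.62 and 2.18, TPM2 at -1.12 and -1.65, and K-ras at 4.24 and 4.71. P9ka42a and S-100 related, both named for S100 calcium-binding proteins, passed in siHMGA2 minus siEGFP as higher. These genes were chosen after their values were seen.

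In the 3 patterns below, the tests of measurement error, of compression, of the empty-vector culture and of errors shared through the dye term were chosen only after the result was seen.

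Features that set ROSEA25 apart from ROSE199 were mostly less extreme with siHMGA2, by a median share of 0.353, from MMP10, CD44 and TGF alpha among the higher to FISP-12, SM22 and P-cadherin among the lower. Random error of the pooled size would leave few features beyond it, but 61 of 83 lay over 2 pooled standard errors closer to ROSE199. The pooled size comes from the HMGA2 and siHMGA2 arrays and does not measure the single siEGFP array. The 83 features were also chosen on that array's value. The siEGFP array's beta actin spots had a log2 SD of 0.16, against 0.07 with the empty vector and 0.24 on siHMGA2 replicate 2. A larger error of the siEGFP array thus stays open. Compression of the log ratios on the siHMGA2 arrays stays open. Scaling all arrays to one spread left a share of 0.116 with 36 of 56 features of opposite sign, where simulation with no change gave a median of 48 of 83 without scaling. Scaling takes away any change common to all features, technical or not, so this fall cannot decide between them. The share was 0.50 in the 42 dimmer of the 83 features and 0.269 in the 41 brighter ones. The siHMGA2 arrays also had the dimmest signals, with a median net intensity of 542 and 724 in the sample channel against 1925 for siEGFP. A partial return toward ROSE199 through a lower HMGA2 level and compressed ratios cannot be told apart here. HMGI-C did not stand out among the others, its share of 0.419 ranking 13 of 35 higher features. The features that moved away from ROSE199, such as P9ka42a and S-100 related, are ones that compression alone would not give. Of these, 5 did so by over 2 pooled standard errors. They were picked after their values were seen and do not show whether the other 76 were compressed.

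The empty-vector cells and the RAS-transformed cells differed from ROSE199 in a related way, a relation that was not among the planned ones. The correlation was 0.49. Errors of the shared arrays and the dye term alone gave 0.20 (0.09 to 0.31), a correlation of errors that cannot be read against it. The covariance was 0.272 against 0.013 simulated. Thrombospondin 1, Collagen alpha, Lox and T16 were lower in both (4 features, 0.772 from independent lists). A dye bias per feature as the only source is argued against by the empty-vector array and the siHMGA2 array with swapped dyes, which still correlated at 0.260. The siEGFP group had no swapped array, so siHMGA2 stands in for it. Part of the 0.49 may still come from dye bias. The other swapped pairs gave 0.191 (empty vector and HMGA2) and 0.188 (siEGFP and HMGA2). The state of the untreated ROSE199 reference RNA stays open, since every array holds it: 6 of the 9 features passing with the empty vector had the same sign in the other 3 groups, all 5 lower ones among them. The low extracellular matrix genes may thus reflect a reference culture rich in matrix transcripts, for instance a denser one, as well as transfection or passage of the cells. A biological explanation was not tested.

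Features higher with HMGA2 were often lower in ROSEA25 cells, although ROSEA25 had HMGI-C itself 5.30-fold higher. The 7 shared features were IGFPBP, P53 binding protein, Peripherin, Ril, Sortilin, Steroid sensitive gene and TEL. Unrelated lists of the same brightness gave as large an overlap in 0.25% of shuffles (median 2, highest 8). That shuffle leaves out errors that the 2 comparisons share through the fitted dye term. With the HMGA2 effects shuffled, array errors added and the fit repeated, 4.4% of 1000 simulations gave as large an overlap (median 3, highest 9), so shared errors stay open as a source of part of it. The state of the single empty-vector culture is argued against for IGFPBP, Peripherin, Sortilin and TEL, 4 of the 7, which also passed as higher against ROSE199, and it stays open for the other 3. With ROSE199 as the baseline the overlap was smaller, 5 features (these 4 and H-rev107) against 2.16 from independent lists. One hypothesis is that HMGA2 may act on these genes in ROSE199 cells while RAS signalling holds them down in ROSEA25 cells. It was not tested, since no group separates RAS from siRNA transfection or the derivation of the line. Whether HMGA2 acts on these genes in ROSEA25 stays open: IGFPBP, Ril, Sortilin and TEL passed as higher with siHMGA2, but compressed ratios would also raise them, and without siHMGA2 replicate 1 Sortilin was at 0.20 and TEL at 0.65. The day of quantification stays confounded with HMGA2 against the empty vector. HMGA2 against ROSE199, where IGFPBP (2.96), TEL (3.20), Peripherin (2.35) and Sortilin (1.04) passed, is read within arrays of 1 day and in both dye orientations.

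The deposited siEGFP ratios differed from the spot intensities by over 1 on the log2 scale at 47 features, against 0 for the empty-vector and HMGA2 arrays and 8 for each siHMGA2 array.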
